A study of Rattus norvegicus with 15 samples.

How the data were processed

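The arrays held total RNA of knee articular cartilage from Sprague-Dawley rats, extracted with Trizol from frozen ground tissue and labelled with biotin, per the labels' protocols. Each of 15 samples was hybridised to an Affymetrix RaGene 2.0 ST array, which carries probe sets for coding and non-coding transcripts. The deposited table holds log2 signals for 36685 probe sets, made by the authors with RMA, per the submitters' processing notes. RMA corrects the background, equalises the distribution of probe signals over arrays and summarises the probes of a probe set, so a change shared by most transcripts is partly removed and a change in the range of an array's signals can remain. The software version, the library file and the genome build are not given in the sources used here. Array medians lay between 4.94 and 5.28, and no further normalization was applied for the main results. For arrays, their number limits the precision.

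Samples were grouped by the stage named in their labels, with 3 samples in each of 5 stages. The labels call the samples of a stage biological replicates and say that knees were harvested individually. T1 replicate 3 is youth in its title, description and stage label and adult in its source name. It was kept in youth, and an alternative placed it with adult. Its mean correlation was 0.977 with the other T1 arrays and 0.963 with the T2 arrays. Ages, sexes and array batches are not given in the sources used here.

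Probe sets were named from the platform's annotation given with the table: 18511 carried 1 gene symbol, 575 several and 17599 none. Only the first were named. Of them, 18394 were matched by Entrez identifier to a RefSeq gene table, which gave the gene class, and 117 were not. Where a gene had several probe sets (291 genes), the probe set with the highest mean over all samples stood for it, which left 18166 genes. In 17 genes, called probe sets moved in opposite directions in some comparison. Long non-coding RNA genes numbered 39 and microRNA genes 363. The RefSeq table also gave the chromosome, start and end of genes, by which the microRNA genes between Dlk1 and Dio3 were taken.

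A linear model with a mean per stage was fitted to all 15 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings). The model pools the spread over stages. Changes are differences of stage means on the log2 scale with limma's moderated standard error. Benjamini-Hochberg adjustment ran over all probe sets within each comparison, and an adjusted p under 0.05 was a call. There were 6 pairwise comparisons and a moderated F test over the 5 stages. Fixed gene lists (35) were tested with limma's camera at a preset correlation of 0.01, for lists with at least 5 measured genes, and adjusted over lists within a comparison. The correlation estimated for each list was an alternative. Long non-coding and coding probe sets were compared with Fisher's exact test, two-sided.

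The lists covered cartilage matrix, chondrocyte transcription factors, growth plate hypertrophy, superficial zone, collagen biosynthesis, matrix proteases, cell cycle, senescence, juvenile growth and imprinted genes, TGF-beta and BMP and Wnt signalling, antioxidant enzymes, autophagy, hypoxia and glycolysis, oxidative phosphorylation, interferon response, inflammatory mediators, complement, circadian clock, immediate early and stress genes, sex-linked genes and known lncRNAs. Lists of other cell types covered skeletal muscle, adipocyte, erythroid, neutrophil and myeloid, B cell, T cell, macrophage, osteoclast, osteoblast, endothelial, smooth muscle, tendon and nerve. Some genes stand in a pair of lists, among them S100a8 and S100a9 (inflammatory and myeloid), C1qa, C1qb and C1qc (complement and macrophage) and Ibsp, Alpl and Sp7 (hypertrophy and osteoblast). Older names were matched through the gene table, which placed the coding gene Uqcc5 in the known lncRNA list through its older name Snhg8, so that 1 of 7 measured members there is coding. A list without it was tested as well, an alternative chosen after seeing the data.

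The genes named per comparison were the 6 called genes with the largest rise and the 6 with the largest fall whose arrays did not overlap, leaving out symbols that start with LOC, RGD, Olr, Mir, Snor or Vom, up to 3 called members of each list with the smallest p, the member with the largest change of a list with no call, the 3 called lncRNA genes with the largest rise and fall, and always Col2a1, Acan, Prg4, Col10a1, Sox9 and Mmp13. For the F test they were the 10 genes with the smallest p. The text gives those that stand out in each comparison. Samples, comparisons, tests, lists, the naming rule and most alternatives were fixed before the data were examined. Gene classes (olfactory receptors, ribosomal proteins, microRNA genes), the loess, covariate and without-T4 alternatives and the level-matched lists other than that of cartilage matrix from T2 to T4 were chosen after seeing the data.

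Alternatives dropped the lowest 25% or 50% of probe sets, tested 1 probe set per named gene, applied quantile normalization, median centring, trend and robust moderation, array weights, a 2-fold minimum or the replicate number as a block, fitted only the groups compared, averaged all probe sets of a gene, moved T1 replicate 3, and left out each array in turn. Those added later were cyclic loess normalization, the olfactory receptor median of each array as a covariate and a fit without the T4 arrays.

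The fit was tested on simulated data with 200 changed probe sets of 36685, in 5 draws. With the same spread on every array, T1 minus T0 had a median of 5 false among 108 calls, and 18% of changes of 2-fold and 86% of changes of 4-fold were recovered. With the measured spread of each array, false calls were 0 of 97 for T1 minus T0, 4 of 112 for T3 minus T2, 22 of 128 for T4 minus T2 and 117 of 238 for T4 minus T3. Limma's pooled spread is too small for the T4 arrays, which vary most, and too large for T0 to T2. The simulated noise was independent between probe sets and only 200 were changed. The simulated shares of false calls therefore do not give those of the real comparisons.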

Results

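Articular cartilage of the right knee of Sprague-Dawley rats was profiled at 5 stages of life, T0 to T4. The labels call T0 newborn and T1 youth. T2 is the adult stage. T3 is an early and T4 a late stage of old age. Articular cartilage covers the joint surface, and its cells, the chondrocytes, make a matrix of type II collagen and aggrecan. Each stage had 3 arrays, named biological replicates in the labels, which gave 15 arrays of total RNA from individually harvested knees. Every array gave a log2 signal for 36685 probe sets, of which 18511 carried a single gene symbol and together named 18166 genes. Array medians lay between 4.94 and 5.28, and the number of arrays limits the precision of every comparison. The series asks how transcripts, long non-coding RNAs among them, change over successive stages.

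The arrays of T0, T1 and T2 each had a standard deviation of 2.02 over probe sets, against 1.89 ± 0.07 at T3 and 1.62 ± 0.13 at T4 (SD, n = 3). Olfactory receptor genes, which serve odour sensing, had a median log2 signal of 2.95 ± 0.07 at T0, 2.90 ± 0.04 at T1, 2.92 ± 0.07 at T2, 3.22 ± 0.21 at T3 and 3.89 ± 0.44 at T4 (1185 genes). Ribosomal protein genes, which every cell transcribes at a high level, had a median of 10.1 ± 0.06 at T0, 9.77 ± 0.04 at T2, 9.83 ± 0.16 at T3 and 8.30 ± 1.41 at T4 (54 genes). The mean correlation between arrays of the same stage was 0.977, 0.975 and 0.975 at T0, T1 and T2, 0.930 at T3 and 0.839 at T4. T4 replicate 1 lay farthest from the others, with a ribosomal protein median of 6.67 and a mean correlation of 0.529 with the T0 to T2 arrays. These values stand beside every comparison with T3 or T4.

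**Figure D1:**
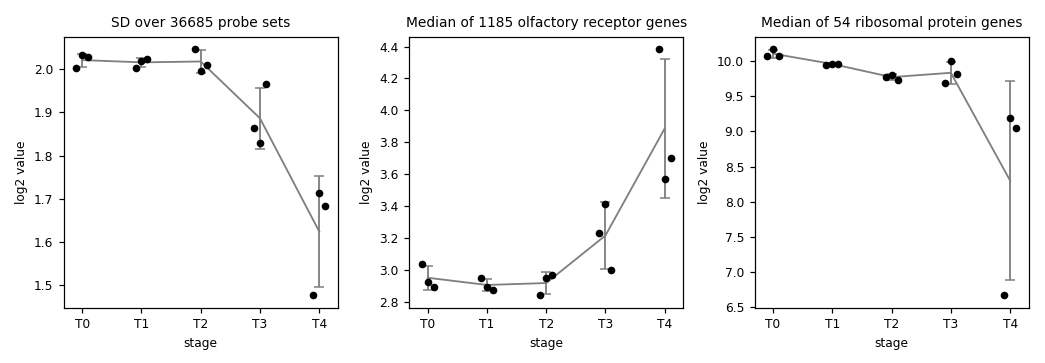
Signal range and 2 gene classes on each array: the standard deviation over 36685 probe sets, the median of 1185 olfactory receptor genes and the median of 54 ribosomal protein genes (log2 values) by stage. Dots are the 3 arrays of a stage, lines join stage means and bars are SDs; the T4 arrays have the narrowest range, the highest olfactory receptor medians and the lowest ribosomal protein medians.

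Over the 5 stages, the 10 genes with the smallest p in limma's moderated F test all had their highest mean in the newborn. They were the perinatal muscle myosin Myh8, the growth factor Igf2, the growth-inhibiting imprinted factor Plagl1, the cartilage matrix genes Epyc and Matn1, the muscle calcium-binding protein Casq2, the angiotensin receptor Agtr2, Fndc3c1 and the microRNA genes Mir493 and Mir539. Igf2 fell from a mean of 12.41 ± 0.02 at T0 to 9.12 ± 0.33 at T1 and 5.50 ± 0.32 at T2 (SD, n = 3), and Matn1 from 10.33 ± 0.03 to 7.76 ± 0.41 and 5.42 ± 0.23. In all, 22043 of 36685 probe sets (60.1%) in 12341 genes passed the F test at a Benjamini-Hochberg adjusted p under 0.05. Of these, 5340 had their highest mean at T0, 1920 at T1, 4235 at T2, 2273 at T3 and 8275 at T4, and 9683 had their lowest mean at T4. A rise or a fall at every step was seen in 3171 of them (14.4%, against 1.67% for a random order of 5 means), 968 upward and 2203 downward. The random order treats the 5 stages alike. Across genes, the changes from T2 to T3 and from T3 to T4 both followed the T0 and T1 level (Spearman correlation -0.58 and -0.71). The excess over 1.67% is therefore no evidence of a steady trend over life. Without the T4 arrays, an alternative chosen after seeing the data, 9366 probe sets passed the F test.

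**Figure D2:**
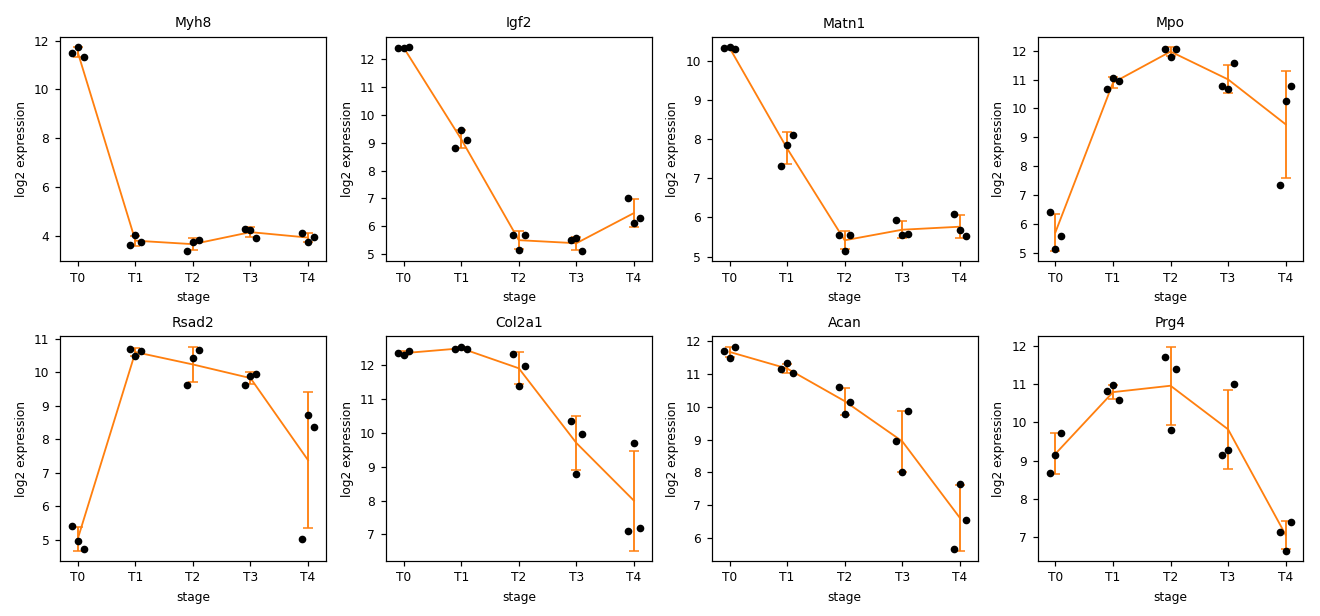
Log2 expression of 8 named genes on every array by stage (T0 newborn, T1 youth, T2 adult, T3 early-stage elderly, T4 latter-stage elderly). Dots are the 3 arrays of a stage, lines join stage means and bars are SDs; Myh8 and Igf2 were highest at T0, Mpo and Rsad2 were low at T0 and high at T1 and T2, and Col2a1, Acan and Prg4 were lowest at T4.

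From newborn to youth, blood and marrow genes rose and skeletal muscle and early growth genes fell. The alpha-defensin Defa5 rose by 6.89 on the log2 scale (SE 0.75, 118-fold), the red cell carbonic anhydrase Car1 by 5.99 (SE 0.77), and the lipoxygenase Alox15 by 5.79 (SE 0.55), each over 3 arrays per stage. The blood cell gene Hemgn rose by 5.71 (SE 0.85), the interferon-induced Rsad2 by 5.57 (SE 0.68) and the red cell anion exchanger Slc4a1 by 5.40 (SE 0.62). Myh8 fell by 7.72 (SE 0.20, 211-fold), Fndc3c1 by 5.63 (SE 0.26), Arhgap36 by 5.09 (SE 0.29), Casq2 by 5.04 (SE 0.29), the muscle calcium pump regulator Sln by 4.90 (SE 0.39) and the cell surface proteoglycan Gpc3 by 4.85 (SE 0.27). The 3 arrays of T0 and the 3 of T1 did not overlap for any of these 12 genes, whose limma adjusted p ran from 5.26e-11 for Myh8 to 0.000525 for Hemgn. In all, 1472 probe sets rose and 1300 fell (2772 of 36685, limma adjusted p under 0.05). The count was 6852 with array weights, where 3327 rose and 3525 fell. It was 5358 with only the 6 arrays compared and 1796 without T0 replicate 2.

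Marker genes of blood and marrow moved together in this comparison. All 8 measured erythroid genes rose, as did 10 of 11 neutrophil and myeloid genes, among them Mpo (5.17, SE 0.64) and Elane (4.17, SE 0.49), which encode enzymes of neutrophil granules. So did 6 of 8 B cell genes, with the B cell receptor component Cd79b (3.44, SE 0.29) and the B cell surface protein Ms4a1 (3.45, SE 0.25). Of 9 T cell genes 4 rose, with the cytotoxic T cell co-receptor Cd8a (1.59, SE 0.20). Adjusted over the list alone, 8, 10, 7 and 5 rose. The medians of these lists were 4.28, 3.46, 2.19 and 0.70, and camera placed them above other genes with adjusted p of 1.06e-12, 5.22e-11, 5.22e-11 and 6.48e-06. With an estimated correlation the erythroid (adjusted p = 0.0301), B cell (adjusted p = 0.0195) and T cell (adjusted p = 0.0195) calls held, and the myeloid call was lost (adjusted p = 0.102 with an estimated correlation). Without the T4 arrays and with an estimated correlation, an alternative chosen after seeing the data, the myeloid list passed (camera adjusted p = 0.0349). Macrophage genes (4 of 12 rose, also adjusted over the list alone, median 0.45, camera adjusted p = 0.00762) and osteoclast genes (2 of 5 rose, 4 adjusted over the list alone, median 1.38, camera adjusted p = 0.0012) shifted up as well. They gave adjusted p = 0.317 and adjusted p = 0.127 with an estimated correlation, and the macrophage median was 0.26 without T0 replicate 3.

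Bone and fat markers rose beside the blood markers. Osteoblast and osteocyte genes rose in 5 of 12 cases (7 adjusted over the list alone, median 0.93, camera adjusted p = 1.19e-05, adjusted p = 0.136 with an estimated correlation). Among them were the bone matrix genes Bglap (2.98, SE 0.35), Dmp1 (3.45, SE 0.50) and Mepe (2.47, SE 0.30). Adipocyte genes rose in 6 of 10 cases (7 adjusted over the list alone, median 1.37, camera adjusted p = 1.64e-07, adjusted p = 0.00894 with an estimated correlation), with the fat cell hormone Adipoq (3.20, SE 0.30). Genes of growth plate hypertrophy and mineralization rose in 4 of 15 cases (5 adjusted over the list alone, median 1.02, camera adjusted p = 0.000367, adjusted p = 0.248 with an estimated correlation). The hypertrophic collagen Col10a1 was among them (1.67, SE 0.38), and its call ended without T0 replicate 2, T1 replicate 1 or T1 replicate 2. Skeletal muscle genes went the other way: 9 of 12 fell, also adjusted over the list alone (median -2.15, camera adjusted p = 1.96e-08, adjusted p = 0.119 with an estimated correlation). The tendon, ligament and synovial fibroblast list shifted down (2 of 12 fell and 1 rose, 6 and 1 adjusted over the list alone, median -0.78, camera adjusted p = 0.0327, adjusted p = 0.343 with an estimated correlation), with the tendon marker Tnmd at -2.64 (SE 0.38), a call lost without T0 replicate 1 (median -0.74, camera adjusted p = 0.053) or T0 replicate 3 (median -0.72, camera adjusted p = 0.0591). Smooth muscle and pericyte genes shifted down too (3 of 7 fell, 4 fell and 1 rose adjusted over the list alone, median -0.55, camera adjusted p = 0.0167, adjusted p = 0.328 with an estimated correlation).

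Cartilage matrix genes were divided between T0 and T1. The leucine-rich proteoglycan Epyc fell by 4.63 (SE 0.22), Matn1 by 2.57 (SE 0.23) and the collagen IX chain Col9a2 by 1.63 (SE 0.23). Of the 18 cartilage matrix genes 5 fell and 1 rose (5 and 2 adjusted over the list alone, median -0.51, camera adjusted p = 0.00364, adjusted p = 0.317 with an estimated correlation). Type II collagen Col2a1 (0.14, SE 0.56), aggrecan Acan (-0.51, SE 0.47), the chondrocyte regulator Sox9 (0.06, SE 0.18), the joint lubricant Prg4 (1.61, SE 0.51) and the collagenase Mmp13 (1.67, SE 0.67) did not pass the test. Collagen and collagen biosynthesis genes fell in 8 of 21 cases (10 adjusted over the list alone, median -0.94, camera adjusted p = 8.59e-07, adjusted p = 0.238 with an estimated correlation). The prolyl hydroxylase P4ha3 stood at -3.02 (SE 0.20) and Col6a2 at -1.32 (SE 0.22). Juvenile growth and imprinted genes fell in 10 of 14 cases (12 adjusted over the list alone, median -1.94, camera adjusted p = 1.21e-14, adjusted p = 0.00894 with an estimated correlation). The imprinted regulator Dlk1 stood at -3.75 (SE 0.28), Igf2 at -3.29 (SE 0.26) and the RNA-binding protein Igf2bp2 at -2.61 (SE 0.25).

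Cell cycle and interferon genes rose over the same step, together with the blood and marrow markers above. In the cell cycle list 13 of 33 rose and none fell (29 adjusted over the list alone, median 1.11, camera adjusted p = 1.21e-14, adjusted p = 0.179 with an estimated correlation). The spindle gene Tpx2 rose by 1.95 (SE 0.25) and the mitotic kinase Plk1 by 1.60 (SE 0.26). In the interferon list 11 of 14 rose (13 adjusted over the list alone, median 1.95, camera adjusted p = 5.22e-11, adjusted p = 0.124 with an estimated correlation). The interferon regulator Irf7 rose by 4.41 (SE 0.58) and the ubiquitin-like modifier Isg15 by 4.38 (SE 0.72). Inflammatory mediators (5 of 16 rose, also adjusted over the list alone, median 0.46), complement (4 of 10, also adjusted over the list alone, median 0.66), with C3 at 3.26 (SE 0.49), and antioxidant enzymes (3 of 15, 5 adjusted over the list alone, median 0.42), with Gpx3 at 2.13 (SE 0.35), shifted up at camera adjusted p of 0.00206, 0.00195 and 0.0182. With an estimated correlation these calls were lost (adjusted p = 0.102, adjusted p = 0.238 and adjusted p = 0.443).

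Senescence and secretory genes (4 of 13 fell, also adjusted over the list alone, median -0.09, camera adjusted p = 0.0276, adjusted p = 0.179 with an estimated correlation) shifted down. The median lay between -0.20 without T0 replicate 2 and -0.02 without T0 replicate 1, where the call was lost (camera adjusted p = 0.0534), or T0 replicate 3, and was -0.15 and -0.17 without T1 replicates 2 and 3. They included the growth factor-binding Igfbp3 at -2.72 (SE 0.24) and the cell cycle inhibitor Cdkn1a at -1.76 (SE 0.22). Circadian clock genes (5 of 13 fell and 1 rose, 7 and 1 adjusted over the list alone, median -0.88, camera adjusted p = 0.0035, adjusted p = 0.224 with an estimated correlation) shifted down too. Per1 stood at -2.18 (SE 0.36) and Dbp at 1.48 (SE 0.29), and the hour of sampling is not given in the sources used here. Dbp lost its call with T1 replicate 3 placed with adult. Oxidative phosphorylation genes (1 of 20 fell, also adjusted over the list alone, median -0.40) shifted down at a camera adjusted p of 0.0043 (adjusted p = 0.502 with an estimated correlation). The other 11 lists were not shifted by camera. Their medians and called members were 0.03 and 1 of 9 for chondrocyte transcription factors, 0.30 and 4 of 10 for the superficial zone, -0.14 and 1 of 14 for matrix proteases, and -0.23 and 3 of 17 for TGF-beta and BMP signalling. They were -0.13 and 3 of 16 for Wnt signalling, 0.05 and 0 of 14 for autophagy, and -0.20 and 1 of 14 for hypoxia and glycolysis. The rest gave -0.24 and 0 of 10 for endothelial, -0.08 and 2 of 8 for nerve, -0.22 and 1 of 16 for immediate early and 0.19 and 0 of 7 for the known lncRNA list. Adjusted over the list alone, these called 1, 7, 4, 7, 5, 0, 2, 0, 3, 0 and 0. The mean opposed the median in sign for the transcription factors and the matrix proteases, where camera pointed down.

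**Figure D3:**
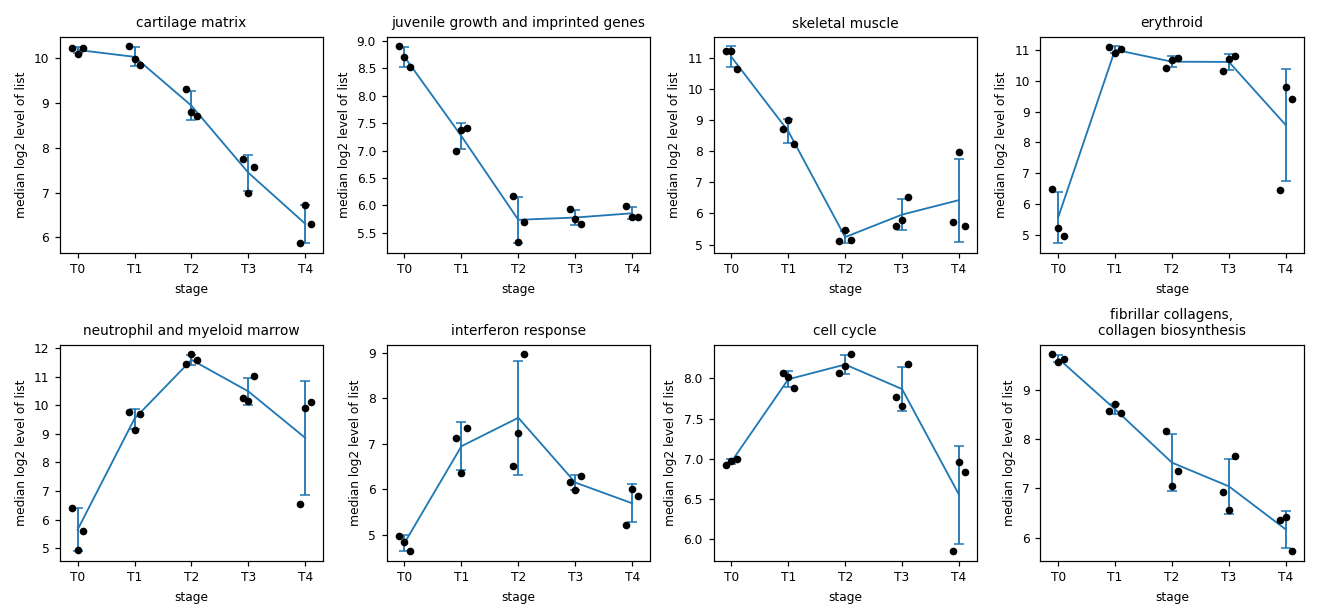
Median log2 level of 8 fixed gene lists on every array by stage (T0 newborn to T4 latter-stage elderly). Dots are the 3 arrays of a stage, lines join stage means and bars are SDs; erythroid and myeloid medians were low at T0 and high at T1 and T2, muscle medians were high at T0 and low at T2, and cartilage matrix medians were lowest at T4.

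From youth to adult, muscle genes and Igf2 fell, and the neutrophil gene Cd177 rose. The muscle contraction genes Myl1 (-4.81, SE 0.52, 28.0-fold), Neb (-4.26, SE 0.39), Acta1 (-4.23, SE 0.31), Tnnc2 (-4.17, SE 0.70) and Actn2 (-4.11, SE 0.53) and the muscle calcium store protein Casq1 (-4.00, SE 0.43) had the largest falls among genes open to naming by the fixed rule, which asks that the arrays of the stages do not overlap. The largest rises among such genes were those of Pilrb2l4 (3.06, SE 0.44, 8.33-fold), the alpha-defensin Defa11 (2.86, SE 0.52) and the haemoglobin-binding Hp (2.74, SE 0.48). They were followed by the neutrophil surface protein Cd177 (2.61, SE 0.38), the organic anion carrier Slco4c1 (2.54, SE 0.34) and Oas1k of the antiviral oligoadenylate synthetase family (2.53, SE 0.48). Igf2 fell by a further 3.62 (SE 0.26), Matn1 by 2.34 (SE 0.23), Col9a2 by 1.24 (SE 0.23) and Col10a1 by 1.73 (SE 0.38), a call that ended in 13 of 20 alternatives. In all, 179 probe sets rose and 148 fell (327 of 36685, limma adjusted p under 0.05, n = 3 arrays per stage), a share of rises of 54.7%. It was 42.9% after quantile normalization, 40.0% without T2 replicate 1, 11.1% with T1 replicate 3 placed with adult and 70.0% with only the 6 arrays compared.

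Skeletal muscle genes fell in 8 of 12 cases (11 adjusted over the list alone, median -3.07, camera adjusted p = 4.05e-27). Adipocyte genes fell in 4 of 10 (6 adjusted over the list alone, median -1.10, camera adjusted p = 6.02e-12), with Adipoq at -2.44 (SE 0.30) and the lipase Lpl at -1.99 (SE 0.25). Juvenile growth genes fell in 2 of 14 (8 adjusted over the list alone, median -0.80, camera adjusted p = 2.44e-09), the second being Plagl1 at -1.68 (SE 0.26), and the median was -0.52 without T2 replicate 2. Smooth muscle and pericyte genes fell in 1 of 7 (6 adjusted over the list alone, median -1.05, camera adjusted p = 3.67e-09), the intermediate filament gene Des at -2.51 (SE 0.33). Wnt signalling genes (1 of 16 fell, 4 adjusted over the list alone, median -0.48, camera adjusted p = 1.13e-06) shifted down. Inflammatory mediators (2 of 16 rose, also adjusted over the list alone, median 0.55, camera adjusted p = 1.78e-06) shifted up, with the nitric oxide synthase Nos2 (1.57, SE 0.32) and the interleukin-1 receptor antagonist Il1rn (1.45, SE 0.30). These 6 calls held with an estimated correlation, the weakest at adjusted p = 0.0481 for smooth muscle. Without the T4 arrays and with an estimated correlation the smooth muscle and Wnt calls were lost (adjusted p = 0.115 and adjusted p = 0.0557) and the myeloid list passed (adjusted p = 0.0418). The interferon list was not shifted (0 of 14 called by limma, also adjusted over the list alone, and 2 at an unadjusted p under 0.05; median 0.17, camera adjusted p = 0.122). Its median ran from -0.38 without T2 replicate 3 to 0.78 without T2 replicate 1.

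The cartilage matrix list shifted down from youth to adult (2 of 18 fell, 7 adjusted over the list alone, median -0.90, camera adjusted p = 2.13e-09, adjusted p = 0.061 with an estimated correlation). Collagen biosynthesis (2 of 21 fell, 14 adjusted over the list alone, median -0.85, camera adjusted p = 1.08e-14, adjusted p = 0.0728 with an estimated correlation), with P4ha3 at -1.12 (SE 0.20), shifted down too. So did hypertrophy (1 of 15, 4 adjusted over the list alone, median -0.87, camera adjusted p = 4.33e-08, adjusted p = 0.0964 with an estimated correlation) and matrix protease genes (1 of 14, 5 adjusted over the list alone, median -0.67, camera adjusted p = 2.57e-05, adjusted p = 0.0964 with an estimated correlation), with the membrane protease Mmp14 at -1.56 (SE 0.30). Col2a1 (-0.59, SE 0.56), Acan (-1.0, SE 0.47), Prg4 (0.17, SE 0.51), Sox9 (-0.21, SE 0.18) and Mmp13 (-1.13, SE 0.67) did not pass the test. Tendon and ligament genes (3 of 12 fell, 5 adjusted over the list alone, median -0.98, camera adjusted p = 2.41e-07, adjusted p = 0.0564 with an estimated correlation), with Tnmd at -3.24 (SE 0.38), moved with them. Endothelial genes did so as well (2 of 10 fell, 6 adjusted over the list alone, median -0.63, camera adjusted p = 1.78e-06, adjusted p = 0.061 with an estimated correlation), with the junction protein Cdh5 at -1.43 (SE 0.31). Myeloid genes shifted up (1 of 11 rose, 7 adjusted over the list alone, median 1.35, camera adjusted p = 7.54e-09, adjusted p = 0.0964 with an estimated correlation), with the granulocyte regulator Cebpe at 1.31 (SE 0.23). The superficial zone (median -0.57, camera adjusted p = 0.0239), TGF-beta and BMP (median -0.40, camera adjusted p = 0.000418) and osteoblast (median -0.70, camera adjusted p = 0.000178) lists shifted down. They gave adjusted p = 0.503, adjusted p = 0.172 and adjusted p = 0.172 with an estimated correlation, and the first call was also lost without T2 replicate 2 (median -0.40, camera adjusted p = 0.354). In 6 lists that were not shifted (antioxidant, B cell, T cell, macrophage, immediate early and known lncRNA genes) the median, the mean and the camera direction differed in sign.

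The youth to adult count moved with single arrays and with a label. T1 replicate 3 is named youth in its title and stage label and adult in its source name. Its Igf2 level was 9.11, against 8.80 and 9.46 on the other T1 arrays and 5.13 to 5.70 on the T2 arrays, and its Matn1 level 8.11, against 7.31 and 7.86 and 5.15 to 5.56. Placed with the adult arrays, it left 9 probe sets and none of the 27 genes named here as changed, while changes such as those of Neb (-3.72), Casq1 (-3.61) and Igf2 (-2.73) kept their direction. Leaving out T1 replicate 1, 2 or 3 or T2 replicate 2 or 3 gave 112, 119, 176, 146 and 108 probe sets, and leaving out T2 replicate 1 gave 370.

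Over the whole way from newborn to adult, 2388 probe sets rose and 2271 fell (4659 of 36685, limma adjusted p under 0.05, n = 3 arrays per stage). Among genes open to naming by the fixed rule, the largest rises were those of the alpha-defensins Defa11 (8.21, SE 0.52, 296-fold) and Defa5 (7.85, SE 0.75), and of Ms4a3 (6.65, SE 0.69), Retnlg (6.53, SE 0.81), Serpinb10 (6.45, SE 0.63) and Mpo (6.24, SE 0.64). The largest falls among them were those of Myh8 (-7.86, SE 0.20, 233-fold), Myl1 (-7.16, SE 0.52), Actn2 (-6.99, SE 0.53), Igf2 (-6.91, SE 0.26), Tnnc2 (-6.80, SE 0.70) and the proteoglycan Kera (-6.72, SE 0.51). Prg4 rose by 1.78 (SE 0.51) and Acan fell by 1.51 (SE 0.47), calls that ended in 6 and 11 of 20 alternatives. Col2a1 (-0.45, SE 0.56), Col10a1 (-0.06, SE 0.38), Sox9 (-0.15, SE 0.18) and Mmp13 (0.54, SE 0.67) did not pass the test. Cartilage matrix genes fell in 12 of 18 cases and rose in 2 (the same counts adjusted over the list alone, median -1.60, camera adjusted p = 1.28e-06, adjusted p = 0.116 with an estimated correlation). Skeletal muscle genes all fell (12 of 12, also adjusted over the list alone, median -5.30, camera adjusted p = 9.96e-17, adjusted p = 0.0393 with an estimated correlation). Of 14 interferon genes 12 rose (13 adjusted over the list alone, median 2.77, camera adjusted p = 1.11e-09, adjusted p = 0.116 with an estimated correlation). Of 33 cell cycle genes 21 rose (29 adjusted over the list alone, median 1.22, camera adjusted p = 1.42e-12, adjusted p = 0.168 with an estimated correlation). For hypertrophy and superficial zone genes, neither shifted, the median and the mean differed in sign.

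From adult to early-stage elderly, the lectin Lgals9 fell by 2.29 (SE 0.28, 4.88-fold), the calpain family member Capn6 by 2.38 (SE 0.38) and the interferon-inducible Ifi27 by 2.36 (SE 0.39). The cartilage matrix gene Matn3 fell by 2.21 (SE 0.37), the neutrophil chemokine receptor Cxcr2 by 2.10 (SE 0.38) and the fatty acyl reductase Far2 by 2.08 (SE 0.33). Hapln1, which links aggrecan to hyaluronan, fell by 1.54 (SE 0.25) and the osteoclast receptor Oscar by 1.52 (SE 0.25). The named genes that rose were Atp6ap1l (2.30, SE 0.40, 4.92-fold), the olfactory receptor Or4c31 (1.73, SE 0.31) and Fbll1 (1.21, SE 0.21). In all, 14 probe sets rose and 41 fell (55 of 36685, limma adjusted p under 0.05, n = 3 arrays per stage), and 7264 had an unadjusted p under 0.05. The share of rises was 25.5%, against 0% after quantile normalization and 38.0% after cyclic loess, and 56.4% with array weights, 53.6% without T3 replicate 3 and 50.8% without the T4 arrays. It was 36.2% with T1 replicate 3 placed with adult, 12.5% with the olfactory receptor median as a covariate, 6.25% with the replicate block, 5.26% without T2 replicate 2 and 0% without T2 replicate 1 or T3 replicate 1.

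Cartilage matrix genes shifted down (2 of 18 fell, 12 adjusted over the list alone, median -1.29, camera adjusted p = 2.31e-08, adjusted p = 0.511 with an estimated correlation), with a median of -0.75 without T3 replicate 2. Interferon genes did so too (1 of 14, 10 adjusted over the list alone, median -1.92, camera adjusted p = 7.76e-08, adjusted p = 0.511 with an estimated correlation). Their array medians had an SD of 1.25 over the 3 T2 arrays and 0.156 at T3, and the change was -1.03 without T2 replicate 3. Hypertrophy genes shifted down as well (0 of 15 by limma, 5 adjusted over the list alone, median -0.70, camera adjusted p = 0.000103, adjusted p = 0.585 with an estimated correlation). Osteoclast genes shifted the same way (1 of 5, 2 adjusted over the list alone, median -1.0, camera adjusted p = 0.00667, adjusted p = 0.511 with an estimated correlation), at -0.61 without T2 replicate 1. So did collagen biosynthesis genes (0 of 21, also adjusted over the list alone, median -0.41, camera adjusted p = 0.0076, adjusted p = 0.676 with an estimated correlation) and cell cycle genes (0 of 33, also adjusted over the list alone, median -0.32, camera adjusted p = 0.0153, adjusted p = 0.728 with an estimated correlation). The collagen call was lost without T2 replicate 1 (median -0.17) or T3 replicate 2 (-0.24), and its median was -0.65 and -0.88 without T3 replicates 1 and 3. The cell cycle call was lost without T2 replicate 3 (-0.27), T3 replicate 1 (-0.25) or T3 replicate 2 (-0.21). At an unadjusted p under 0.05 there were 6 hypertrophy, 5 collagen and 5 cell cycle genes. Skeletal muscle genes (0 of 12, also adjusted over the list alone, 3 unadjusted, median 0.64, camera adjusted p = 0.00937, adjusted p = 0.639 with an estimated correlation) shifted up, a call lost without T3 replicate 3 (median 0.47). So did the known lncRNA list (0 of 7, 1 adjusted over the list alone, 1 unadjusted, median 0.37, camera adjusted p = 0.0321, adjusted p = 0.511 with an estimated correlation), lost without T2 replicate 1 or T3 replicate 1 (median 0.34 in both). In it Uqcc5 is a coding gene, and the gene table names 1 member Rpph1 but gives it the class of Rmrp, so which of these RNAs it measures is not settled. Without Uqcc5 the list had 6 genes, a median of 0.47 and a camera adjusted p of 0.0325 (adjusted p = 0.502 with an estimated correlation). Col2a1 (-2.21, SE 0.56), Acan (-1.22, SE 0.47), Prg4 (-1.14, SE 0.51) and Col10a1 (-1.68, SE 0.38) did not pass the test. Neither did Sox9 (-0.11, SE 0.18), Mmp13 (-0.90, SE 0.67), the hypertrophic channel gene Panx3 (-2.38, SE 0.44) or the telomerase RNA Terc (1.52, SE 0.28). Genes of low level moved up and genes of high level down, with a median change of 0.28 in the lowest 10% of genes by T0 and T1 level and -0.43 in the highest 10%. In 4 lists that were not shifted (TGF-beta, oxidative phosphorylation, endothelial and immediate early genes) the median, the mean and the camera direction differed in sign.

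The count of this step depended on single arrays and on the fit. By limma it was 0 without T2 replicate 3, without T3 replicate 2 and with only the 6 arrays compared, where 5661, 4195 and 6886 probe sets had an unadjusted p under 0.05. It was 15 without T2 replicate 1, 10 without T3 replicate 1, 4165 without T3 replicate 3, 10464 with array weights and 1895 without the T4 arrays, which then no longer enter the pooled spread. All of the 11 genes named as changed lost their call in at least 1 alternative, Lgals9 in 3 of 20.

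From early-stage to latter-stage elderly, many cartilage matrix genes and the joint lubricant Prg4 fell and some olfactory receptor genes rose. The small proteoglycan Dcn fell by 2.96 (SE 0.51, 7.77-fold), the cartilage lectin Clec3a by 2.86 (SE 0.49), Prg4 by 2.75 (SE 0.51), the matrix protein Chad by 2.64 (SE 0.49), Acan by 2.34 (SE 0.47) and Hapln1 by 1.75 (SE 0.25). The mast cell protease Mcpt10 (-2.96, SE 0.41), the secretory pathway gene Tmed2 (-2.83, SE 0.65), Mmp13 (-2.49, SE 0.67), Col2a1 (-1.70, SE 0.56) and Col10a1 (-1.22, SE 0.38) fell as well, and Sox9 (0.46, SE 0.18) did not pass the test. The Col2a1 call ended in 9 of 19 alternatives, among them those without T3 replicate 1, T3 replicate 3, T4 replicate 1 or T4 replicate 3, and its levels overlapped, with 8.80 on T3 replicate 2 and 9.70 on T4 replicate 2. The Col10a1 call ended in 6, among them those without T3 replicate 3 or T4 replicate 3, and the Mmp13 call in 4. Of the 6 largest rises among genes open to naming by the fixed rule, 4 were olfactory receptors, led by Or13n4b (3.56, SE 0.42, 11.8-fold), and the others were the trace amine receptor Taar7a (3.40, SE 0.26) and Rps15al1 (3.32, SE 0.36). In all, 6042 probe sets rose and 9451 fell (15493 of 36685, limma adjusted p under 0.05, n = 3 arrays per stage), a share of rises of 39.0%. It was 51.4% after quantile normalization, 53.7% after cyclic loess, 51.9% with the olfactory receptor median as a covariate, 51.6% with only the 6 arrays compared and 18.2% without the lowest 50% of probe sets.

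The change followed signal level over all genes. The median change was 0.35 in the lowest 10% of 18166 genes by T0 and T1 level and -1.51 in the highest 10%. Of 1185 olfactory receptors 435 rose and 31 fell, while 33 of 54 ribosomal protein genes fell and 4 rose. Beside these, cell cycle genes fell in 31 of 33 cases (32 adjusted over the list alone, median -1.32, camera adjusted p = 5.55e-07, adjusted p = 0.752 with an estimated correlation), with Tpx2 at -1.58 (SE 0.25). Oxidative phosphorylation genes fell in 16 of 20 (17 adjusted over the list alone, median -1.37, camera adjusted p = 0.00133, adjusted p = 0.752 with an estimated correlation), with the succinate dehydrogenase subunit Sdhb at -1.55 (SE 0.23). Antioxidant genes fell in 12 of 15 (14 adjusted over the list alone, median -1.41, camera adjusted p = 0.00398, adjusted p = 0.752 with an estimated correlation), at -0.84 without T4 replicate 1. Cartilage matrix genes fell in 10 of 18 cases (13 adjusted over the list alone, median -1.09, camera adjusted p = 0.0337) and collagen biosynthesis genes in 11 of 21 (12 adjusted over the list alone, median -0.80, camera adjusted p = 0.036), both at adjusted p = 0.752 with an estimated correlation. Matrix proteases fell in 10 of 14 (also adjusted over the list alone, median -1.66, camera adjusted p = 0.0489) and macrophage genes in 7 of 12 (also adjusted over the list alone, median -1.13, camera adjusted p = 0.0337), both again at adjusted p = 0.752 with an estimated correlation. The cartilage matrix call was also lost without T3 replicate 1, T4 replicate 1 (median -0.92 in both) or T4 replicate 3 (-1.17), and the collagen call without T3 replicate 3 (-0.59), T4 replicate 1 (-0.80) or T4 replicate 3 (-0.77). The protease call was lost without T3 replicate 2 (-1.82), T3 replicate 3 (-1.31), T4 replicate 1 (-1.10) or T4 replicate 3 (-1.57), and the macrophage call without T3 replicate 2 (-1.08) or T4 replicate 1 (-0.83). Superficial zone genes fell in 5 of 10 (also adjusted over the list alone, median -1.29), and that list was not shifted (camera adjusted p = 0.0557). After cyclic loess the medians of the cartilage matrix and collagen lists turned to 0.27 and 0.18 and the changes of Col2a1 and Col10a1 to 0.33 and 0.28. Of the blood markers, 4 of 8 erythroid genes (5 adjusted over the list alone, median -1.62, camera adjusted p = 0.146) and 4 of 11 myeloid genes (also adjusted over the list alone, median -1.39, camera adjusted p = 0.146) fell. Of 12 muscle genes 2 rose (also adjusted over the list alone, median 0.41, camera adjusted p = 0.0947), with Acta1 at 1.55 (SE 0.31). The growth factor Tgfb1 fell by 1.51 (SE 0.19). Of the sex-linked list, only the Y chromosome gene Uty was measured: it was at 7.89 ± 0.31 at T0, 7.26 ± 0.62 at T3 and 5.52 ± 0.78 at T4, a fall of 1.75 (SE 0.35) from T3 to T4. In 6 lists that were not shifted (chondrocyte transcription factors, senescence, Wnt, adipocyte, T cell and nerve genes) the median, the mean and the camera direction differed in sign.

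In data simulated with the spread of each array, 117 of 238 calls from T3 to T4 were false (median of 5 draws of 200 changed probe sets), against 5 of 102 with equal spread. Far more probe sets were called in the real data, so this share does not give the share of real calls that are false. With the olfactory receptor median of each array as a covariate, an alternative chosen after seeing the data, 541 probe sets were called, and with only the 6 arrays compared 2532. Over the 25 genes given by their values for this step, the covariate took the median size of change from 2.49 to 1.5. The median SE went from 0.40 to 0.47, and all 25 kept their sign. For some genes the sign then says little, since the change was smaller than its SE. These included Tmed2 (-0.17, SE 0.37), Snhg4 (-0.16, SE 0.52), Col2a1 (-0.18, SE 0.69) and Mmp13 (-0.44, SE 0.77). Others, such as Hapln1 (-1.70, SE 0.38) and Taar7a (2.79, SE 0.33), kept most of their change.

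**Figure D4:**
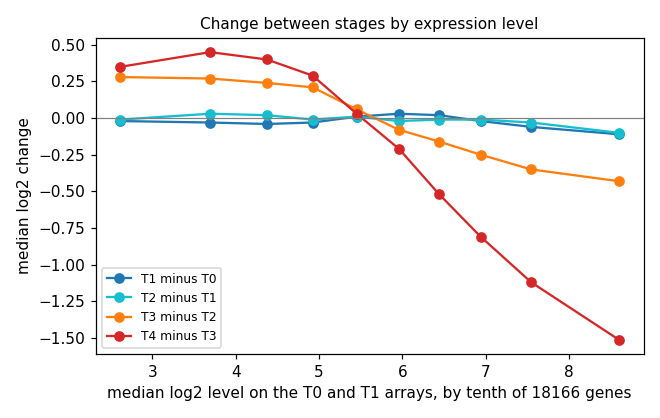
Median log2 change between successive stages (vertical axis) in each of 10 groups of 18166 genes ordered by level, placed at the group's median log2 level on the T0 and T1 arrays (horizontal axis), with a line per comparison. T1 minus T0 and T2 minus T1 stayed between -0.11 and 0.03 at all levels, and T4 minus T3 went from 0.35 in the lowest group to -1.51 in the highest.

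From adult to latter-stage elderly, most cartilage matrix genes and Prg4 fell and many olfactory receptor genes rose. Clec3a fell by 4.59 (SE 0.49, 24.2-fold), the collagen-binding proteoglycans Fmod by 4.30 (SE 0.62) and Prelp by 4.22 (SE 0.58), and the bone and cartilage proteoglycan Omd by 4.10 (SE 0.44). Chad fell by 4.0 (SE 0.49), Col2a1 by 3.91 (SE 0.56), Prg4 by 3.89 (SE 0.51), Acan by 3.56 (SE 0.47), Mmp13 by 3.38 (SE 0.67) and Col10a1 by 2.90 (SE 0.38). Sox9 (0.35, SE 0.18) did not pass the test. Ifi27 fell by 2.96 (SE 0.39) and Acta1 rose by 2.40 (SE 0.31). Among genes open to naming by the fixed rule, the largest rises were those of olfactory receptors, with Or13n4b at 4.14 (SE 0.42), Or8c10b at 4.09 (SE 0.38) and Or10ak7f at 3.95 (SE 0.37), a class in which 652 of 1185 rose and 14 fell. In all, 9960 probe sets rose and 10768 fell (20728 of 36685, limma adjusted p under 0.05, n = 3 arrays per stage), and median centring moved the median of all probe sets from 0.07 to -0.12. The share of rises was 48.1%, against 39.2% after median centring and 23.3% without the lowest 50% of probe sets.

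Cartilage matrix genes fell in 15 of 18 cases (also adjusted over the list alone, median -2.76, camera adjusted p = 0.000453) and hypertrophy genes in 12 of 15 with 1 rise (also adjusted over the list alone, median -2.38, camera adjusted p = 0.00904). These and the other 11 list calls of this comparison were lost with an estimated correlation (adjusted p = 0.666 with an estimated correlation for each of the 13). Superficial zone genes fell in 7 of 10 (also adjusted over the list alone, median -1.93, camera adjusted p = 0.022). Interferon genes fell in 12 of 14 with 1 rise (also adjusted over the list alone, median -2.36, or -1.54 without T2 replicate 3, camera adjusted p = 0.017) and cell cycle genes in 31 of 33 (32 adjusted over the list alone, median -1.65, camera adjusted p = 1.33e-06). The collagen biosynthesis, matrix protease, antioxidant, oxidative phosphorylation, autophagy, complement and macrophage lists were shifted down as well. Against random lists of genes of similar T0 and T1 level, none of these lay below percentile 2.5. Their percentiles were 96.8, 17.9, 32.7, 86.5, 34.3, 34.9 and 10.4 in the order named. Matched on the T2 level, matrix proteases stood at 1.72. The hypertrophy (12.4) and superficial zone (48.9) lists did not lie below 2.5 either. Cartilage matrix (1.5), interferon (0) and cell cycle (0.8) lists did. The skeletal muscle list was shifted up (4 of 12 rose, 3 adjusted over the list alone, median 1.07, camera adjusted p = 0.0149). The muscle call was lost without T4 replicate 2 (median 0.39) and the complement call (-1.14) without T2 replicate 1 (-0.84), T2 replicate 3 (-1.07), T4 replicate 1 (-1.10) or T4 replicate 2 (-1.20). Without T4 replicate 1 the autophagy median went from -1.61 to -1.06 and the macrophage median from -1.60 to -0.90. Ribosomal protein genes fell in 29 of 54 cases and rose in 6, and the median change went from 0.65 in the lowest 10% of genes by level to -1.92 in the highest 10%. Senescence, juvenile growth, T cell and known lncRNA genes were not shifted, and their median and mean differed in sign. In data simulated with the spread of each array and few changed probe sets, 22 of 128 calls were false (median of 5 draws), a share that cannot be carried to the real calls. With the olfactory receptor median as a covariate 141 probe sets were called and none of the 15 genes named here as changed. Or8c10b then stood at 3.28 (SE 0.71, from 0.38), Clec3a at -2.61 (SE 0.76, from 0.49), Omd at -2.41 (SE 0.70, from 0.44) and Mmp13 at -0.42 (SE 0.98, from 0.67). Over the 15 genes and Sox9 the median size of change went from 3.93 to 2.44 and the median SE from 0.45 to 0.75. This did not hold for each gene. Acta1 (2.83, SE 0.60, from 0.31) and Ifi27 (-2.86, SE 0.79, from 0.39) kept about the size of their change and lost their calls with a larger SE. Of the covariate's variance over the arrays, 81.0% lay between stages.

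Long non-coding RNA genes, the class the series title names, were called mainly in comparisons with T4, and so were protein-coding genes. Probe sets without a single gene symbol were not classed. None of the 41 lncRNA probe sets passed limma's test from T0 to T1 (0 of 41, against 1967 of 17746 protein-coding probe sets; Fisher's exact p = 0.0202, two-sided), from T1 to T2 or from T2 to T3. For these steps 2, 3 and 7 had an unadjusted p under 0.05. From T0 to T2, 2 of 41 fell (Vof16 at -2.30, SE 0.38, and Meg3 at -0.95, SE 0.25), against 3351 of 17746 coding probe sets called (Fisher's exact p = 0.0162, two-sided). From T3 to T4, 12 rose and 2 fell: the largest rise was that of AA926063 (2.37, SE 0.25, 5.16-fold) and the larger fall that of Snhg4, a host gene of small nucleolar RNAs (-2.31, SE 0.59). With the olfactory receptor median as a covariate, AA926063 stood at 1.81 (SE 0.32) and Snhg4 at -0.16 (SE 0.52). From T2 to T4, 22 rose and 2 fell. The shares called were 34.1% of lncRNA and 46.7% of coding probe sets from T3 to T4 (Fisher's exact p = 0.118, two-sided). From T2 to T4 they were 58.5% and 63.9% (Fisher's exact p = 0.516, two-sided). The F test called 24 of 41 lncRNA (58.5%) and 12096 of 17746 coding probe sets (68.2%), an odds ratio of 0.659 (95% interval 0.339 to 1.31, Fisher's exact p = 0.184, two-sided), and 0.24 (p = 0.00573) without the lowest 50% of probe sets. Mean levels were 4.99 for lncRNA and 5.65 for coding probe sets, and the groups of genes with median levels of 4.92, 5.45 and 5.96 had median changes of 0.50, 0.08 and -0.29 from T2 to T4. Genes are not independent, so these p are descriptive.

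The change from newborn to youth was set against that from adult to latter-stage elderly. Across 18166 genes, these changes, which share no array, had a Pearson correlation of -0.261 and a Spearman correlation of -0.193. Genes are not independent replicates. Regrouping the arrays gave correlations with an SD of 0.187 and a highest other absolute value of 0.328. The sign of a regrouped correlation depends on which group is subtracted, so only sizes can be compared.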

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

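Cyclic loess, the olfactory receptor covariate, the fits without T4 and the known lncRNA list without its coding gene were chosen after seeing the data. Of named genes, 39 of 41 calls held in every alternative for T1 minus T0, 13 of 15 for T2 minus T0, 6 of 24 for T4 minus T3, and 0 of 27, 0 of 11 and 0 of 15 for T2 minus T1, T3 minus T2 and T4 minus T2. All 27 calls ended with T1 replicate 3 placed with adult, and all 15 with the olfactory receptor covariate. Leaving out an array ended 12 of the 27, all of the 11 and 0 of the 15 in at least 1 fit. The background, taken as the olfactory receptor median, was highest at T4 (3.89 against 2.92 at T2), and this limits what those arrays show. Where no construction is named, the cause was not tested.

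Counts of changed probe sets moved by over 1.5 times as follows. With 1 probe set per named gene, fewer are tested: the F test called 13159, T3 minus T2 118, T4 minus T3 9039 and T4 minus T2 12050. Without the lowest 25% of probe sets T3 minus T2 called 135. Without the lowest 50% the F test called 14012, T3 minus T2 146, T4 minus T3 10241 and T4 minus T2 12321, camera shifted 5, 2 and 2 lists in these 3 comparisons, and the lncRNA odds ratio was 0.24. A 2-fold minimum left 10277 for T4 minus T3. With the 2 compared groups only in the fit, T1 minus T0 called 5358, T2 minus T0 7131, T2 minus T1 596, T3 minus T2 0 (limma, 6886 at an unadjusted p under 0.05) and T4 minus T3 2532. Array weights gave 6852, 9230, 2381 and 10464 for T1 minus T0, T2 minus T0, T2 minus T1 and T3 minus T2. Quantile normalization gave 147 for T2 minus T1 and 10 for T3 minus T2, median centring 99 and trend and robust moderation 85 for T3 minus T2. With T1 replicate 3 placed with adult, T1 minus T0 called 1777 and T2 minus T1 9. Median centring moved the median of all probe sets from 0.09 to -0.04 for T3 minus T2 and from 0.07 to -0.12 for T4 minus T2.

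With an estimated correlation, camera shifted 5 lists for T1 minus T0, 6 for T2 minus T1, 0 for T3 minus T2, 0 for T4 minus T3, 5 for T2 minus T0 and 0 for T4 minus T2. Without the T4 stage and with an estimated correlation it shifted 6, 5, 0 and 7 for T1 minus T0, T2 minus T1, T3 minus T2 and T2 minus T0.

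Without the T4 stage the F test called 9366, T2 minus T1 604 and T3 minus T2 1895. Cyclic loess normalization gave 517 for T2 minus T1 and 242 for T3 minus T2, and 1 list for T4 minus T3 and 2 for T4 minus T2. It turned Col2a1 (0.33), Col10a1 (0.28) and the cartilage matrix (0.27) and collagen (0.18) medians of T4 minus T3, the collagen median of T4 minus T2 (0.15) and the rank of oxidative phosphorylation (-0.06). With the olfactory receptor median as covariate, the F test called 8094, T2 minus T1 685, T3 minus T2 16, T4 minus T3 541 and T4 minus T2 141, with 1 and 6 lists for the last 2. It turned cell cycle in T3 minus T2 (0.15) and, in T4 minus T2, cell cycle (-0.11), antioxidant (-0.11), autophagy (-0.26), oxidative phosphorylation (0.25), erythroid (0.93) and myeloid (0.73) lists in rank or median.

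Leaving out each array in turn gave 1796 (without T0 replicate 2) to 2223 for T1 minus T0, 108 (without T2 replicate 3) to 370 for T2 minus T1, 0 (without T2 replicate 3, 5661 unadjusted in limma) to 4165 (without T3 replicate 3) for T3 minus T2, 11534 to 17507 for T4 minus T3, 3508 to 4176 for T2 minus T0, 17626 to 21690 for T4 minus T2 and 19908 to 23151 for the F test. T2 minus T1 was 112, 119, 176 and 146 without T1 replicates 1, 2 and 3 and T2 replicate 2, and T3 minus T2 was 15, 10 and 0 without T2 replicate 1, T3 replicate 1 and T3 replicate 2. Shifted lists ranged from 21 to 24, 16 to 20, 6 to 12, 4 (without T4 replicate 1) to 8, 21 to 25 and 11 to 14 for T1 minus T0, T2 minus T1, T3 minus T2, T4 minus T3, T2 minus T0 and T4 minus T2. The interferon median of T2 minus T1 ranged from -0.38 (without T2 replicate 3) to 0.78 (without T2 replicate 1). The correlation ranged from -0.281 to -0.236 and the lncRNA odds ratio from 0.544 to 0.739.

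The replicate numbers do not pair the arrays: the median correlation of deviations was -0.0066 for 30 pairs of the same number and 0.0033 for 60 others. With the replicate block T3 minus T2 called 32 and the other counts stayed within 1.5 times.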

Other observations

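Of the tests in this part, those of the signal range, of T4 replicate 1, of the share of cartilage cells and of the growth programme were chosen after the result was seen, as were the microRNA genes and all level-matched lists except cartilage matrix from T2 to T4.

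MicroRNA genes that lie between the imprinted genes Dlk1 and Dio3 fell together from newborn to youth, a set chosen after the values of Mir493 and Mir539 were seen. Of 53 such genes, 40 fell and 0 rose by limma's test (median -1.89, range -4.62 to 0.11), with Mir493 at -4.49 (SE 0.18) and Mir539 at -4.62. Of 310 other microRNA genes, 27 fell and 3 rose (median -0.11). The odds ratio was 31.6 (Fisher's exact p = 3.41e-24, two-sided), and 39.8 from newborn to adult, where 41 of the 53 fell. Neighbouring genes are not independent, so this p is descriptive. From newborn to youth Dlk1 itself fell by 3.75 (SE 0.28), and the lncRNA gene Meg3 of the same region was at -0.36 and did not pass the test. From newborn to adult Meg3 was called as falling, as given above.

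Set against 10000 random lists of genes of similar level on the T0 and T1 arrays, 6 of 34 lists had a mean below the central 95% of such lists from T2 to T3 and 8 a mean above it. Those below were the cartilage matrix (mean -1.10, against a median of -0.43 for matched lists), interferon (-1.58 against -0.09), hypertrophy (-0.86 against -0.39), osteoclast (-1.10 against -0.16), inflammatory (-0.36 against -0.04) and T cell (-0.24 against 0.06) lists. Those above were skeletal muscle, oxidative phosphorylation, known lncRNA, adipocyte, erythroid, smooth muscle, immediate early and endothelial lists. With lists matched on the T2 level, 5 lay below, all but the inflammatory list, and 6 above, and the matched medians were -0.41 for cartilage matrix and -0.36 for interferon. From T3 to T4, 2 lists lay below, cell cycle (percentile 0.03) and myeloid (2.41), and 8 above. Without T4 replicate 1 these stood at 4.7 and 97.9, the 2 below were superficial zone (0.94) and matrix proteases (1.05), and 5 lay above. With lists matched on the T2 level 3 lay below, neither cell cycle (30.3) nor myeloid (98.1) among them. The cartilage matrix mean from T3 to T4 was -1.25 against -1.52, at percentile 94.9, and 5.73 without T4 replicate 1. These percentiles describe genes on these arrays and carry no error between animals.

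Many probe sets changed at T4 (20728 from T2 to T4). The count without T4 replicate 1 was 18121, so that array alone is not the cause. A narrower signal range on the T4 arrays, which may come from RNA quality or hybridisation, stays open for part or all of the changes. Across genes the T4 minus T2 change had a Spearman correlation of -0.76 with the level on the T0 and T1 arrays (-0.56 after quantile normalization, -0.22 after cyclic loess). Of the calls 15363 were kept after quantile normalization and 11839 after cyclic loess. Kept calls cannot decide the question, since a trend with level remained after both. With the olfactory receptor median, itself highest at T4, as a covariate, 141 probe sets were called, and the median SE of named genes went from 0.45 to 0.75. A loss of cartilage matrix transcripts beyond that of genes of the same level also stays open, since the list's mean of -2.35 lay at percentile 1.5 of matched lists (0 without T4 replicate 1). Age and the tissue's makeup at T4 are untested biological explanations, and both kinds may act together.

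Marrow and blood genes rose from T0 to T1. A lower share of cartilage cells with all other cell types unchanged would raise muscle markers too. The skeletal muscle median was -2.15, with a largest SD between arrays of 0.39, a fall known before this test. It goes against that explanation only as stated, with all other cell types unchanged. Whether the share of cartilage cells fell while that of muscle also changed was not tested and stays open. Marrow or blood cells in the dissected tissue remain a candidate explanation that no test here decides, since the rise of their genes is the observation itself. Among these genes the signal went from 10.19 to 12.52 (Hbb-b1), from 10.18 to 12.43 (Hba-a1), from 5.72 to 10.89 (Mpo) and from 8.51 to 9.76 (Ebf1). Growth of marrow and bone under the joint surface with age is an untested biological explanation, and interferon, osteoblast and adipocyte genes rose over the same step.

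Cell cycle genes rose from T0 to T1. A growth programme that raises the juvenile growth and imprinted list was not seen, since its median was -1.94, with a largest SD between arrays of 0.24. The fall of this list was known before the test, and its genes were highest in the newborn. Other growth of young tissue was not tested and stays open. Dividing marrow cells in the dissected tissue cannot be told apart from division of cartilage cells here. Within stages, over the 9 arrays of T0 to T2, the cell cycle median had a Pearson correlation of -0.09 with the marrow medians (exact permutation p = 0.708, two-sided, 216 rearrangements) and a Spearman correlation of -0.167 (exact permutation p = 0.657), and r was 0.0958 without the 2 arrays farthest from the median. The marrow medians varied little within T1 and T2, which keeps it open. At T0 they deviated by 0.852, -0.525 and -0.327 from the stage mean in replicates 1, 2 and 3. The cell cycle medians there deviated by -0.0343, 0.00494 and 0.0294, and r was 0.218 without T0.

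Other splits of the 15 arrays gave at most 10096 probe sets in the F test, against 22043 for the real stages. Of 100 splits 1, the real one, was as large, the smallest share that 100 splits can give. This argues against a random grouping of the arrays. It cannot tell stage from the array quality that differed at T3 and T4. For the correlation of early and late change (-0.261), 9 of 100 pairs of splits gave an absolute value as large and the highest other was 0.328, so chance cannot be excluded. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real and highest other counts of probe sets were 2772 and 0 for T1 minus T0, 327 and 0 for T2 minus T1, 55 and 0 for T3 minus T2, 15493 and 55 for T4 minus T3, 4659 and 1 for T2 minus T0 and 20728 and 0 for T4 minus T2, and 1 split of 10 was as large in each. For gene lists the real and highest other counts were 23 and 19, 16 and 22, 8 and 14, 7 and 12, 24 and 21, and 13 and 19 in the same order, with 1, 4, 6, 7, 1 and 3 splits as large. Counts of shifted lists by camera's preset correlation were thus often larger in regrouped arrays than in the real stages.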
